A study of Mus musculus with 12 samples.

How the data were processed

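Mouse limb mesenchyme at E14.5 was profiled by RNA sequencing in 12 libraries, 6 from cells expressing bovine Creb5 with GFP (iCreb5) and 6 from cells expressing tdTomato, sorted by fluorescence per the labels' protocols. Each library was assigned to its group and litter from its title and batch label. The title numbers and batch labels mark 4 sets of libraries, whereas the design text speaks of 6 litters. The 4 sets were taken as litters here. Each set has its own batch label, so litter and batch cannot be told apart. Whether a library is a single embryo or a pool is not given in the sources used here. Libraries with *Xist*, named here outside the rule below, at 2254 or more had the Y-linked *Ddx3y* at 0. Those with *Ddx3y* at 1931 or more had *Xist* at 1.837 or less. These values argue against pools of mixed sex, while pools of the same sex stay possible. With the 4 sets taken as litters, the libraries of litter 3 are separate samples from a shared litter. The p-values measure the spread between these 12 libraries.

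Reads were processed by the authors. FastQC, STAR, Salmon and DESeq2, and the genome build mm10, are named without versions or roles in the submitters' processing notes. Strand use in counting and the handling of reads from the bovine transgene are not given in the sources used here. The deposited table holds normalised signal per gene, that is, gene counts divided by a size factor for each library, judged from the deposited values: every library's values were whole multiples of 1 unit. Dividing by that unit gave whole reads for 100% of values within a tolerance of 1e-06. If the authors rounded estimated counts before normalising, the recovered reads are those rounded counts. The table lists 54532 genes, 23386 of them at 0 in all 12 libraries and 123 without a symbol. A second deposited table, of stage P0, has 8 columns that match no labelled sample, and it was not used in any step. Recovered depth ran from 9.02 to 53.3 M reads (M for 1000000) per library. A library's value at 3 reads lay between 1.48 and 8.38 deposited units, which bounds the precision for weakly expressed genes and covers counting error only.

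Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) on log2(value + 1), with no covariate. The 16733 genes with a value of at least 10 in at least 6 of the 12 libraries were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold for every adjusted p given. A fold change is a ratio of geometric means of value + 1. The added 1 shrinks the change of weakly expressed genes, while for genes with a wide spread between libraries, such as *Mmp13*, *Ptprc* and *Il1a*, the fold is larger than the ratio of the group means. The plan assumed either normalised values or whole-number counts, and the normalised-value test was used because the table is normalised. Within-litter comparisons used litter 3 alone (3 against 3) and litters 4 to 6 with litter as a term (3 against 3). Their difference was tested as an interaction. As alternatives, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads and called 640 higher and 472 lower, and 955 higher and 732 lower. Library totals were compared by exact two-sided permutation over all splits of the 12 libraries.

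The groups, the design, the alternatives and 29 gene lists were fixed before the data were examined. The lists were drawn from textbook knowledge and cover the joint interzone, articular surface and synovium, chondrocyte, hypertrophic chondrocyte, osteoblast, tendon and ligament, dermal and loose connective tissue, limb position, BMP, Wnt, TGF-beta, hedgehog, and FGF and EGF receptor signalling. They also cover cAMP and immediate early genes, the CREB/ATF and AP-1 family, matrix proteases, cell cycle, unfolded protein and integrated stress response, p53, interferon, glycolysis and hypoxia, and sex-linked genes. Lists for other cells cover skeletal muscle, endothelium, red cells, leukocytes, epidermis, Schwann cells and melanoblasts, and neurons. Some genes stand in more than 1 list, among them *Thbs4*, *Ibsp*, *Spp1*, *Mmp13*, *Fgf18* and *Ihh*. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry. Of the 12 lists that camera called, only the chondrocyte, hypertrophic, osteoblast, leukocyte, and Schwann cell and melanoblast lists held with an estimated correlation. A list of imprinted genes was written later, after values had been seen.

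Genes named in the text follow a fixed rule. It takes *Creb5* and *Prrx1*, and then the 12 largest rises and 12 largest falls. These had to have an adjusted p under 0.05, a mean value of at least 50, groups that do not overlap and a symbol that is not a predicted or clone name. From each list it takes up to 4 members past the threshold with the largest change and the 2 most abundant members not past it, and members where a count of 5 or fewer is given. The text prints part of these, 1 gene taken by the rule is not reported here, and says where a gene outside the rule was chosen after its values were seen. Coordinates come from GENCODE mouse release M21 on mm10, matched by gene identifier. Of the 54532 identifiers, 54495 matched.

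Litter pairs the libraries by their labels. As a check of the pairing, deviations from the group means had a mean correlation of 0.0627 within a litter and -0.0298 between litters. For the 6 pairs with the same number they ran from 0.000309 to 0.346, and 2 of 6 iCreb5 libraries correlated best with their own number. With litter as the replicate block 859 genes were higher and 728 lower, and with litter 3 also averaged to 1 value per group 494 and 388.

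The tests were checked on simulated data for the same 16733 genes, with 200 genes changed by known folds. The simulation was not repeated. Every gene was given the same spread between libraries, the median of the data, so recovery is overstated for genes with a wider spread. The 6 against 6 limma test recovered 18% of 1.5-fold, 86% of 2-fold and 100% of 4-fold and 8-fold changes, with 0.654% of calls false. The litter 3 test recovered 58% of 2-fold changes and the litters 4 to 6 test 46%. The alternatives changed the pseudocount, the filter, the scaling, the block, the weights, the variance model and the tool, and left out each library and each litter in turn. Added after seeing the data were sex and the leukocyte score as covariates, and leaving out tdTomato 3a and 5b or iCreb5 5 and 6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the table, the permutation tests and the figures.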

Results

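RNA was sequenced from mesenchymal cells of E14.5 mouse limbs that Cre recombinase, driven by the Prrx1 limb enhancer, had switched to 1 of 2 transgenes at the Rosa26 locus. The iCreb5 cells expressed a tagged bovine form of the transcription factor Creb5 together with GFP, and the tdTomato cells expressed a red fluorescent protein in its place. Littermates carried either transgene, and cells were sorted by fluorescence. The 12 libraries comprised 6 iCreb5 libraries and 6 tdTomato libraries. With litters read from title numbers and batch labels, litter 3 gave 3 libraries of each group, and litters 4, 5 and 6 gave 1 of each. Every litter so read had its own batch label, so a litter difference may be a batch difference. Whole reads could be recovered from the deposited normalised read counts. With M for 1000000, they came to 30.5 ± 9.89 M per iCreb5 library and 25.8 ± 15.1 M per tdTomato library (mean ± SD, n = 6, exact two-sided permutation test, p = 0.511). The shallowest library, tdTomato 3a, held 9.02 M reads and the deepest, tdTomato 3b, held 53.3 M. The other tdTomato libraries held 18.9 M (3c), 27.6 M (4a), 18.4 M (5b) and 27.4 M (6d). The iCreb5 libraries held 28.7 M (3a), 21.6 M (3b), 49.2 M (3c), 23.1 M (4a), 29.4 M (5) and 30.9 M (6). A single read was worth between 0.494 and 2.79 deposited units. Summed normalised counts were 24.9 ± 0.377 M in iCreb5 and 26.1 ± 1.04 M in tdTomato (n = 6, exact permutation p = 0.0065, where 0.00216 is the smallest p the design allows). Genes above 0, the share of the 10 most abundant genes and the share of mitochondrial transcripts gave exact permutation p of 0.318, 0.141 and 0.691 (n = 6). On the second principal component the lowest libraries were iCreb5 5 (-58.1) and tdTomato 5b (-54.0), both of litter 5, and iCreb5 6 (-34.3), while the first component ran from -73.7 to -13.6 in tdTomato and from 9.11 to 47.0 in iCreb5.

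The comparison of iCreb5 with tdTomato cells asked what a raised level of Creb5 does to gene expression in limb mesenchyme, including expression of *Creb5* itself. *Creb5* (ENSMUSG00000053007, mm10 chromosome 6, 53287270 to 53700376) had a normalised count of 2799 ± 214 in iCreb5 and 1803 ± 299 in tdTomato (mean ± SD, n = 6), 1.57-fold higher, and the groups did not overlap. Its log2 change was 0.65 ± 0.12 (SE; adjusted p = 0.00219), with 0.78 within litter 3 (adjusted p = 0.0188) and 0.52 within litters 4 to 6 (adjusted p = 0.0501). How reads of the bovine transgene were assigned is not given in the sources used here, so the count may hold transcripts of the transgene as well as of the mouse gene. *Prrx1* (ENSMUSG00000026586, chromosome 1, 163245119 to 163313710), whose enhancer drove Cre, measured 4158 ± 575 in iCreb5 and 4986 ± 943 in tdTomato (n = 6; log2 change -0.25 ± 0.14 (SE), adjusted p = 0.352).

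Among the 16733 genes tested, 648 were higher and 477 lower in iCreb5, of which 382 and 239 differed by 2-fold or more. The rises included the joint lubricant gene *Prg4*, the interzone ligand *Wnt16* and every leukocyte marker examined, and the falls included 21 of 24 cartilage genes and 11 of 13 measured osteoblast genes. With libraries rescaled to equal totals, 799 genes were higher and 382 lower, so that 67.7% of the calls were rises instead of 57.6%. With litter as the replicate block, 859 were higher and 728 lower, and with litter 3 also averaged to 1 value per group 494 were higher and 388 lower. Within litter 3 alone 395 genes were higher and 292 lower, and within litters 4 to 6 alone 320 were higher and 368 lower. The 1125 genes called in the pooled comparison had a change of the same sign in both sets of litters, which their selection in the pooled data favours. Across all 16733 genes, which are not independent replicates, the log2 changes of the 2 sets had a correlation of 0.487. In 794 of 16733 genes (4.75%) every iCreb5 library lay on one side of every tdTomato library, where chance gives 0.216%. Of these, 716 were among the called genes. Without litter 3, which leaves 3 libraries per group and no block, 85 genes were higher and 57 lower. Without tdTomato 3a and 5b, the shallowest library and the one farthest out on the principal components, 562 were higher and 425 lower. Without iCreb5 5 and 6, which held the most *Ccl4* and *Il1a*, 638 were higher and 501 lower.

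The largest rise among abundant genes was that of *Tbx22* (ENSMUSG00000031241, chromosome X, 107667964 to 107688978), a T-box transcription factor gene needed for palate formation. Its normalised count was 687 ± 177 in iCreb5 and 23.2 ± 16.6 in tdTomato (n = 6), 33.3-fold higher on the log2(value + 1) scale (adjusted p = 7.61e-07). *Prg4* (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which encodes the joint lubricant lubricin, rose 10.7-fold, from 85.4 ± 31.2 to 908 ± 245 (adjusted p = 7.96e-07), with log2 changes of 3.59 in litter 3 and 3.24 in litters 4 to 6. The neuropeptide gene *Nts* was 13.8-fold higher. The homeobox gene *Dbx2* was 11.5-fold higher, at 776 ± 151 against 69.0 ± 24.8. *Klhl1* was 10.2-fold higher and *Fbxo32*, a ubiquitin ligase gene of muscle atrophy, 9.60-fold higher. Of the 12 largest rises, 5 were genes best known from macrophages and other leukocytes. They were *Il1a* (16.2-fold), *C5ar1* (12.9-fold), *Trem2* (12.6-fold), *Ms4a6b* (11.4-fold) and *Ccl4* (9.58-fold), with adjusted p between 0.000196 and 0.00394. They varied widely between libraries: *Ccl4* measured 684 ± 714 in iCreb5 and 49.7 ± 21.3 in tdTomato.

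The largest fall was that of *Serpina3n*, a protease inhibitor gene (chromosome 12, 104406729 to 104414329), at 25.6 ± 10.5 in iCreb5 and 427 ± 126 in tdTomato (n = 6). It was 16.4-fold higher in tdTomato (log2 change -4.04 ± 0.27 (SE), adjusted p = 3.44e-07). Genes of mineralised tissue and cartilage followed, with the bone matrix gene *Dmp1* 10.8-fold, the bone proteoglycan gene *Omd* 6.45-fold and the cartilage gene *Ucma* 6.03-fold higher in tdTomato. The complement gene *C4b* was 8.48-fold higher in tdTomato. The neighbouring *Pou3f3* and *Pantr1*, a POU-domain transcription factor gene and a long noncoding RNA gene, were 6.09-fold and 5.20-fold higher in tdTomato. *Ccn6* (5.45-fold), *Klk10* (4.79-fold) and *Itgbl1* (4.62-fold) were also higher in tdTomato, with adjusted p from 0.000118 to 0.000277 for these 3 genes. *Dhx58os* was 6.11-fold higher in tdTomato, but its reads may belong to the overlapping gene because use of strand in counting is not given in the sources used here. The histone gene *Hist1h2br* was 9.64-fold higher in tdTomato (adjusted p = 0.0206). It belongs to a family of near-identical genes, so its value is uncertain, and without tdTomato 6d its adjusted p was 0.0524. Reads of *Serpina3n*, *Ms4a6b* and *C4b* could likewise be shared with close relatives.

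**Figure D1:**
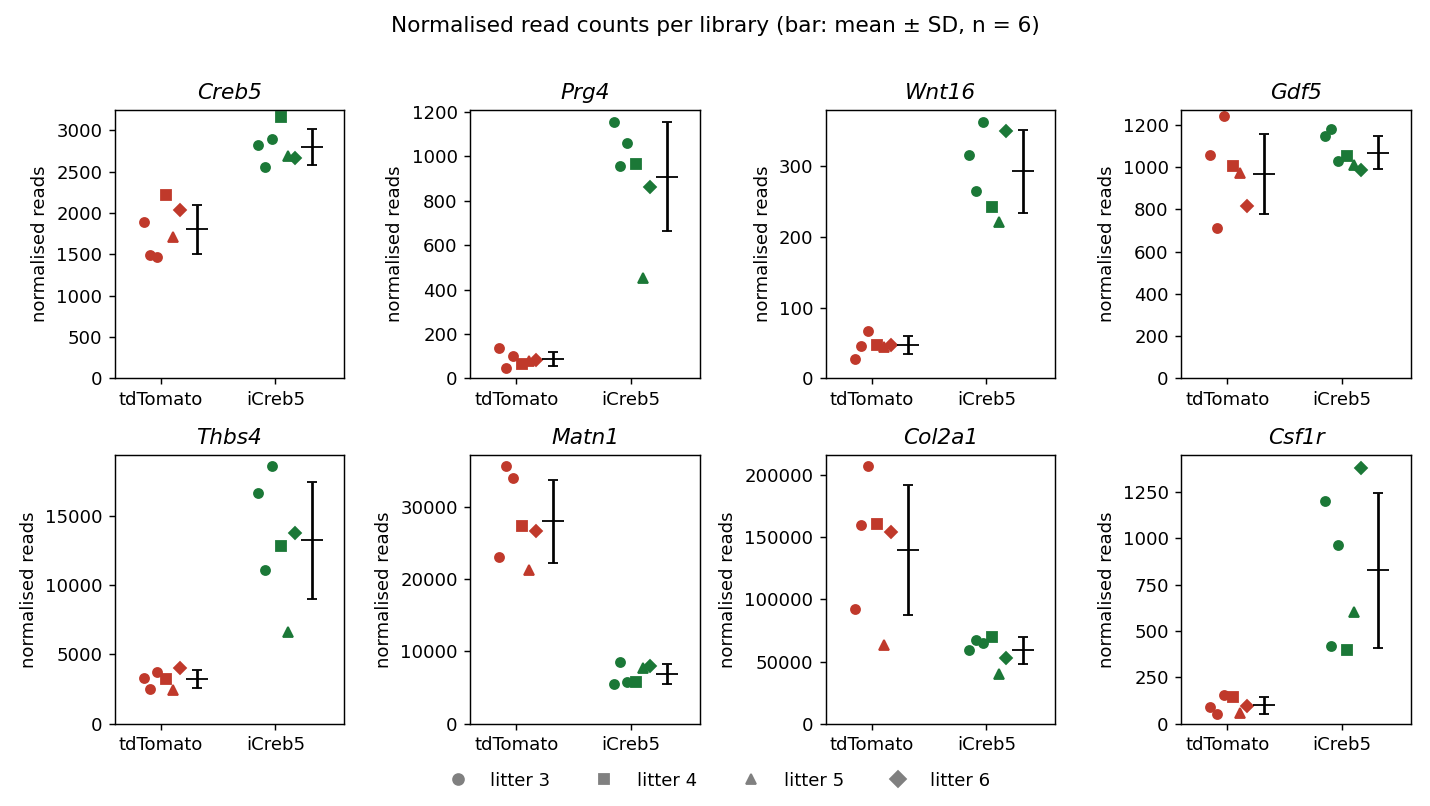
Normalised read counts (deposited units, linear axes from 0) of 8 genes in the 6 tdTomato and 6 iCreb5 libraries, with a point per library shaped by litter and the mean ± SD (n = 6). *Prg4*, *Wnt16*, *Thbs4* and *Csf1r* lie higher in iCreb5, *Matn1* and *Col2a1* lower, *Creb5* was 1.57-fold higher and *Gdf5* did not pass the threshold (adjusted p = 0.585).

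The series title names the regulatory program of the joint interzone, the band of cells between future bones from which joints form. Of 20 interzone genes, 4 were higher in iCreb5, 1 was lower and 15 did not pass the threshold (5 higher and 2 lower when adjusted over the list alone). *Wnt16*, a Wnt ligand gene of the interzone, rose 6.24-fold from 46.6 ± 12.5 to 292 ± 58.3 (n = 6, adjusted p = 1.65e-06). *Osr2*, a zinc-finger gene of developing synovial joints, was 2.03-fold higher (adjusted p = 4.9e-06), and the secreted Wnt modulator *Sfrp2* was 1.45-fold higher (adjusted p = 0.00216). *Gdf6*, a growth factor gene of joint formation, was 2.72-fold higher at 200.4 ± 110 against 67.6 ± 23.8 (adjusted p = 0.0196). The call for *Gdf6* was lost without iCreb5 3b (adjusted p = 0.0539) and within litters 4 to 6 (adjusted p = 0.18). The homeobox gene *Barx1* fell, and was 2.96-fold higher in tdTomato (adjusted p = 0.000583). *Gdf5*, the classical interzone marker, named here after its values were seen, measured 1068 ± 79.0 in iCreb5 and 967 ± 187 in tdTomato (n = 6; log2 change 0.16 ± 0.13 (SE), 95% interval -0.12 to 0.44, adjusted p = 0.585). As a set the interzone list had a median log2 change of 0.12, and limma's camera gave an adjusted p of 0.114. It gave 0.342 as adjusted p with an estimated correlation, and adjusted p = 0.0372 without iCreb5 5. Limma's fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00761. The median was 0.16 in litter 3 (adjusted p = 0.0239) and 0.04 in litters 4 to 6 (adjusted p = 0.65). Counts were 4 higher and 1 lower without tdTomato 3a and 5b, and 5 higher and 1 lower without iCreb5 5 and 6. Leukocyte markers rose in the same libraries, with a median log2 change of 2.75.

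Of 18 genes of the articular surface and synovium, 4 were higher in iCreb5, 0 were lower and 14 did not pass (4 higher and 1 lower when adjusted over the list alone). Besides *Prg4* these were *Thbs4*, which encodes a thrombospondin of tendon and cartilage matrix, the serine protease gene *Htra1* and the chondrogenic growth factor gene *Fgf18*. *Thbs4* rose 4.00-fold, from 3204 ± 647 to 13260 ± 4237 (n = 6, adjusted p = 2.39e-05). *Htra1* was 2.44-fold higher (adjusted p = 3.21e-05) and *Fgf18* had a log2 change of 0.58 ± 0.12 (SE; adjusted p = 0.00595). The list's median log2 change was 0.09, with adjusted p = 0.0781 by camera, adjusted p = 0.345 with an estimated correlation and adjusted p = 0.00761 by fry. Camera passed the threshold when tdTomato 3b (adjusted p = 0.0352), iCreb5 3a (0.0495) or iCreb5 5 (0.040) was left out. The median was -0.03 in litter 3 (adjusted p = 0.284) and 0.07 in litters 4 to 6 (adjusted p = 0.0266). The count was 4 higher and 0 lower both without tdTomato 3a and 5b and without iCreb5 5 and 6. The median log2 change of the leukocyte markers across the same libraries was 2.75.

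Cartilage genes fell together. Of 24 genes of cartilage matrix and its regulators, 21 were lower in iCreb5, 0 were higher and 3 did not pass the threshold (23 lower when adjusted over the list alone), with a median log2 change of -1.41. *Matn1* (chromosome 4, 130944385 to 130955475), a cartilage matrix protein gene, measured 6843 ± 1360 in iCreb5 and 27970 ± 5781 in tdTomato (n = 6), 4.08-fold higher in tdTomato (adjusted p = 7.61e-07). *Chad* was 4.25-fold and *Comp* 4.07-fold higher in tdTomato, and both encode cartilage matrix proteins. Of members named after their values were seen, *Col2a1*, the main collagen gene of cartilage, was 2.24-fold higher in tdTomato, the proteoglycan gene *Acan* 3.06-fold and the master regulator *Sox9* 1.72-fold. *Nkx3-2*, a regulator of early chondrocytes, had a log2 change of 0.16 ± 0.26 (SE; adjusted p = 0.812). *Sox6*, a partner of *Sox9*, had -0.61 ± 0.19 (SE; adjusted p = 0.0725), and passed in 8 of 36 other settings. Among these were edgeR (adjusted p = 0.0373), DESeq2 (0.0103), the set without tdTomato 3b (0.00153) and litters 4 to 6 alone (0.00425), but not litter 3 alone (0.714). Camera gave an adjusted p of 1.34e-37 for the list, 0.00187 as adjusted p with an estimated correlation, and fry gave 6.61e-07. The median was -1.47 within litter 3 and -1.35 within litters 4 to 6, and 21 genes were lower without tdTomato 3a and 5b or without iCreb5 5 and 6. Leukocyte markers moved the opposite way in the same libraries, with a median log2 change of 2.75.

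Of 12 genes of hypertrophic chondrocytes, the cells that mature before bone forms, 8 were lower, 1 was higher and 3 did not pass (10 lower and 1 higher when adjusted over the list alone). The collagenase gene *Mmp13* was 7.06-fold and the secreted phosphoprotein gene *Spp1* 4.49-fold higher in tdTomato (adjusted p = 0.00374 and 0.000109). *Slc26a7*, an anion transporter gene, was the riser at 3.74-fold higher in iCreb5 (adjusted p = 0.000156). *Pth1r*, the parathyroid hormone receptor gene, had a log2 change of -0.20 ± 0.13 (SE; adjusted p = 0.491). Of 13 measured osteoblast genes, 11 were lower, 0 were higher and 2 did not pass (11 lower when adjusted over the list alone). Besides *Dmp1*, the homeobox gene *Dlx6* was 4.46-fold higher in tdTomato (adjusted p = 0.0111), and the osteoblast regulator *Sp7*, named after its values were seen, 2.61-fold (adjusted p = 0.00178). *Ibsp*, a bone sialoprotein gene on both lists, was 4.17-fold higher in tdTomato with wide spread, at 4048 ± 3999 in iCreb5 and 15740 ± 13270 in tdTomato (adjusted p = 0.0423). Its call was kept when tdTomato 5b, tdTomato 6d, iCreb5 4a or iCreb5 6 was left out and lost without any of the other 8 libraries (adjusted p 0.0508 to 0.101). It was also lost with edgeR (adjusted p = 0.0735) and DESeq2 (0.0563). *Col1a1*, the main collagen gene of bone, which other mesenchyme also expresses, had a log2 change of -0.00 ± 0.29 (SE; adjusted p = 0.998), and *Phex* had -0.32 ± 0.20 (SE; adjusted p = 0.435). Median log2 changes were -1.28 and -1.45 for the hypertrophic and osteoblast lists, with camera adjusted p of 2.04e-07 and 5.62e-14. Both lists had an adjusted p = 0.0224 with an estimated correlation. Medians were -1.58 and -1.66 within litter 3, and -0.94 and -1.19 within litters 4 to 6. Without tdTomato 3a and 5b, 7 hypertrophic and 10 osteoblast genes were lower, and without iCreb5 5 and 6 it was 7 and 9. Leukocyte markers rose in the same libraries, with a median log2 change of 2.75.

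**Figure D2:**
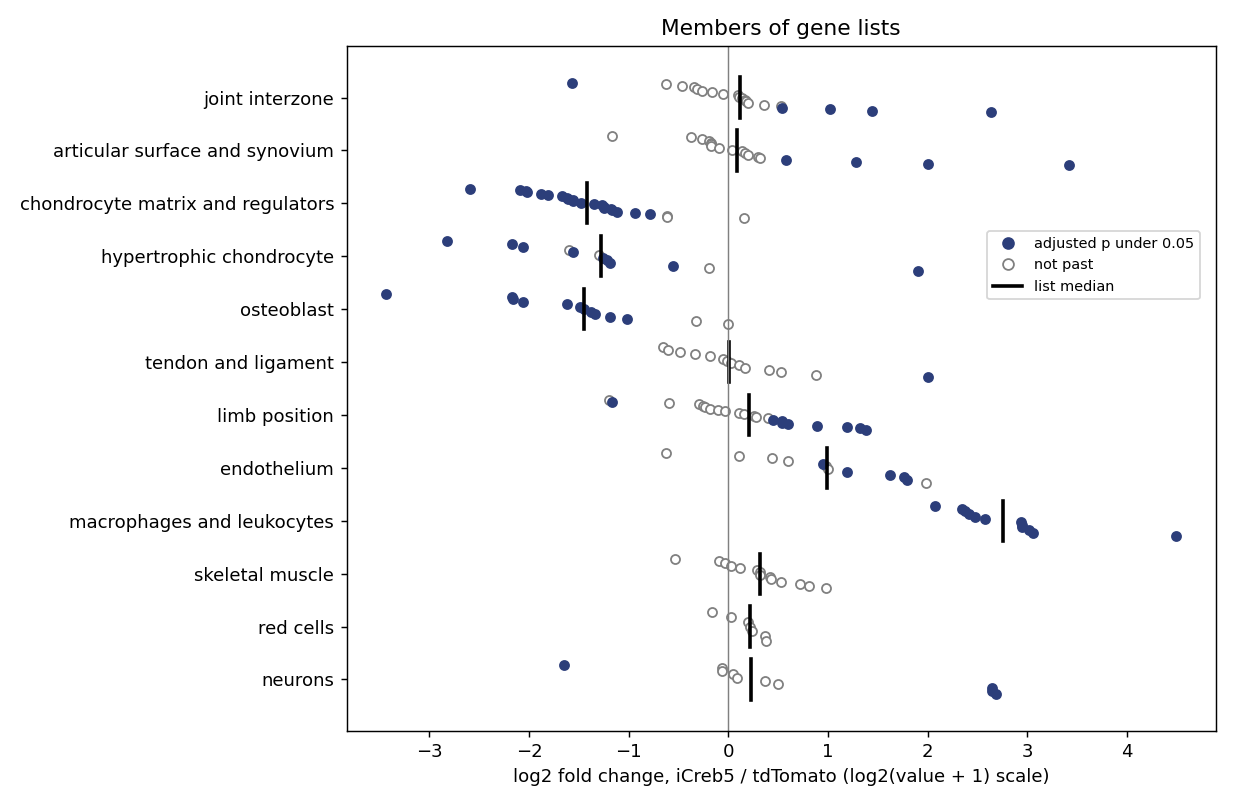
Log2 fold change of iCreb5 over tdTomato for each measured member of 12 gene lists, with filled points for adjusted p under 0.05 and a bar at each list's median. The chondrocyte, hypertrophic and osteoblast lists lie mostly below 0 (medians -1.41, -1.28 and -1.45), and the leukocyte list lies above 0 (median 2.75).

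Most genes of tendon and loose connective tissue did not pass the threshold. Of 14 tendon and ligament genes 1 was higher, *Thbs4*, and 13 did not pass (2 higher when adjusted over the list alone, camera adjusted p = 0.659). Of 16 genes of dermal and loose connective tissue 1 was higher and 2 were lower, both over all genes and when adjusted over the list alone (camera adjusted p = 0.516). *Cd34*, a surface sialomucin gene, was 1.44-fold higher (adjusted p = 0.0151). *Mfap5*, a microfibril gene, was 1.94-fold higher in tdTomato (adjusted p = 0.038), and the retinoic acid binding protein gene *Crabp1* 1.54-fold (adjusted p = 0.0339). The call for *Mfap5* held without tdTomato 3c, tdTomato 4a, iCreb5 5 or iCreb5 6 and was lost without any of the other 8 libraries (adjusted p up to 0.097) and with edgeR (0.0674). The call for *Crabp1* held without tdTomato 3a, tdTomato 3c, tdTomato 5b or iCreb5 5 and was lost without any of the other 8 (adjusted p up to 0.0814).

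Genes that mark position in the limb changed, led by the 5′ Hoxd genes, which pattern the distal limb. Of 22 such genes 8 were higher, 1 was lower and 13 did not pass (9 higher and 3 lower when adjusted over the list alone). *Hoxd11* rose 2.60-fold, from 246 ± 51.9 to 628 ± 65.2 (n = 6, adjusted p = 6.81e-05), *Hoxd12* rose 2.50-fold and *Hoxd10* 2.28-fold. These genes and *Hoxd13* lie side by side on chromosome 2 between 74668310 and 74695105. *Lhx9*, a LIM homeobox gene, was 2.25-fold higher in tdTomato (adjusted p = 0.000397). The other 5 risers, named after their values were seen, were *Hand2* (1.86-fold), *Hoxd13* (1.51-fold), *Tbx4* (1.46-fold), *Hoxa11* (1.45-fold) and *Hoxa10* (1.37-fold). *Hoxd13* (adjusted p = 0.0319) kept its call without tdTomato 3c, tdTomato 5b, iCreb5 3c or iCreb5 4a and lost it without any of the other 8 libraries (adjusted p up to 0.0749). *Tbx4* (adjusted p = 0.033) kept its call without tdTomato 3a, 3b or 3c or iCreb5 5 or 6 and lost it without any of the other 7 (adjusted p up to 0.0831). Camera gave an adjusted p of 0.0277 for the list, and adjusted p = 0.202 with an estimated correlation. The median log2 change was 0.21, with 0.06 in litter 3 (adjusted p = 0.0317) and 0.30 in litters 4 to 6 (adjusted p = 0.0942). The call was also lost without litter 3 (adjusted p = 0.11) and with litter 3 averaged (0.0572). Counts were 7 higher and 1 lower without tdTomato 3a and 5b, and 6 higher and 1 lower without iCreb5 5 and 6, where camera gave an adjusted p of 0.0716. Leukocyte markers rose in the same libraries, with a median log2 change of 2.75.

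**Figure D3:**
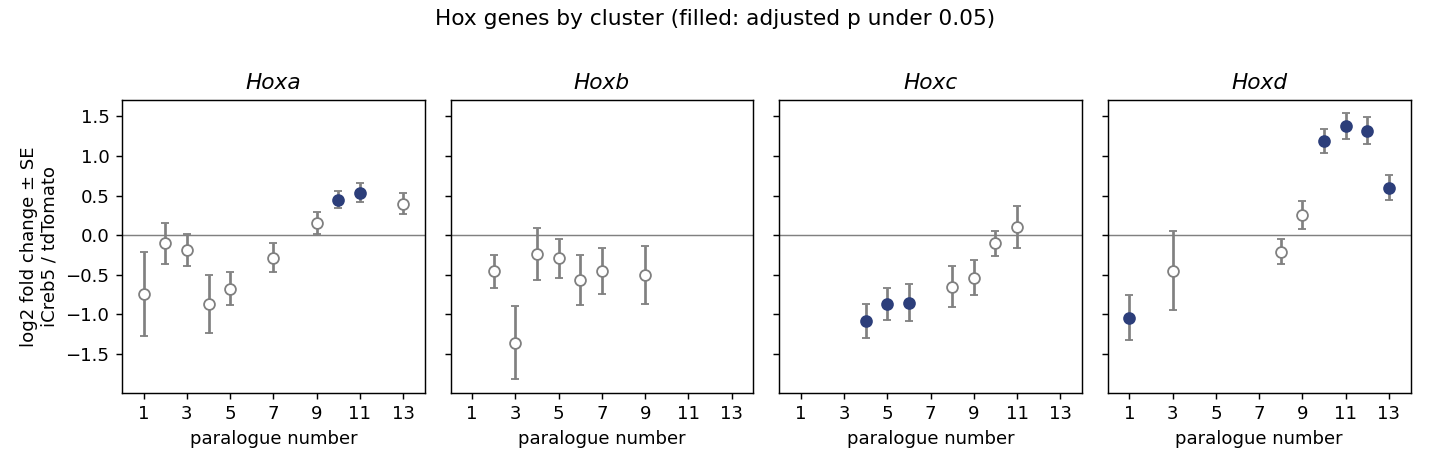
Log2 fold change of iCreb5 over tdTomato (± SE) of the measured Hox genes by paralogue number, for the 4 clusters, with filled points for adjusted p under 0.05. Of 9 genes of paralogue groups 10 to 13, 6 were higher, and of 23 genes of groups 1 to 9, 4 were lower, or 2 lower with equal library totals and 5 with quantile normalisation.

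Signalling genes changed in small numbers. Of 19 BMP genes 1 was higher and 2 were lower, the same when adjusted over the list alone (camera adjusted p = 0.129, but 0.040 without iCreb5 5, 0.0147 in litter 3 alone and 0.0136 without iCreb5 5 and 6). The ligand gene *Bmp5* was 3.17-fold higher in tdTomato (adjusted p = 2.82e-06), and the BMP antagonist gene *Grem1* was 1.73-fold higher in iCreb5 (adjusted p = 0.0111). *Bmper*, 1.51-fold higher in tdTomato (adjusted p = 0.0415), kept its call without tdTomato 5b or iCreb5 3b and lost it without any of the other 10 libraries (adjusted p up to 0.0979). Of 15 measured Wnt response genes 1 was higher and 1 lower (1 and 2 when adjusted over the list alone, camera adjusted p = 0.239, but 0.0296 in litters 4 to 6). These were the Wnt antagonist *Dkk2* (1.58-fold higher in iCreb5) and the Wnt deacylase gene *Notum* (2.13-fold higher in tdTomato). Of 16 TGF-beta genes only the ligand gene *Tgfb2* passed, 1.67-fold higher, also when adjusted over the list alone (camera adjusted p = 0.352). Of 10 hedgehog genes the ligand gene *Ihh* was lower, 2.32-fold higher in tdTomato (adjusted p = 0.0218, and 0.0546 without tdTomato 3b). Adjusted over the list alone, 2 hedgehog genes were higher and 2 lower (camera adjusted p = 0.615). Of 17 genes of FGF and EGF receptor signalling 2 were higher and 1 was lower (2 and 3 when adjusted over the list alone, camera adjusted p = 0.516). They were *Fgf18*, the phosphatase gene *Dusp4* (2.22-fold higher in iCreb5) and the feedback inhibitor *Spry1* (1.40-fold higher in tdTomato). None of 20 cAMP-responsive and immediate early genes passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.623). That list's camera direction turned between settings: higher without litter 3 (adjusted p = 0.0201) and in litters 4 to 6 (0.00986), lower without iCreb5 5 and 6 (0.0139) and with a leukocyte covariate (6.77e-05). Of 18 relatives of Creb5 in the CREB/ATF and AP-1 family, *Maf* was lower, 1.56-fold higher in tdTomato (adjusted p = 0.0132), also when adjusted over the list alone. The median log2 change of this family was -0.18, with camera adjusted p = 0.0277 and adjusted p = 0.234 with an estimated correlation. The camera call was lost without tdTomato 4a (adjusted p = 0.0644), tdTomato 5b (0.0639), iCreb5 3b (0.0709) or litter 4 (0.0785) and in litter 3 alone (0.143).

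Of 17 measured matrix proteases and inhibitors 1 was higher and 4 were lower (3 and 5 when adjusted over the list alone). The membrane metalloproteinase gene *Mmp16* was 1.72-fold higher in iCreb5. *Mmp9*, a gelatinase gene, was 4.25-fold higher in tdTomato, as were *Mmp13*, *Adamts12* (1.86-fold) and the inhibitor gene *Timp1* (1.80-fold). The list's median log2 change was 0.02, its mean -0.31 and the direction of its test downward, with camera adjusted p = 0.516. Of 20 cell cycle genes the kinase gene *Aurkb* was higher, 1.31-fold (adjusted p = 0.0175, and 0.0517 without iCreb5 3b). Adjusted over the list alone, 3 were higher and 2 lower. Camera gave the cell cycle list a median log2 change of 0.16 and adjusted p = 0.0306, with adjusted p = 0.255 with an estimated correlation. That call was lost without tdTomato 3c (adjusted p = 0.0703), tdTomato 4a (0.0836), iCreb5 3b (0.073), litter 3 (0.235) or litter 4 (0.0785), in litters 4 to 6 (0.172) and with litter 3 averaged (0.0611).

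Of 14 measured genes of the unfolded protein and integrated stress response 2 were lower and 0 higher, the same when adjusted over the list alone. The asparagine synthetase gene *Asns* was 1.45-fold and the stress protein gene *Nupr1* 1.89-fold higher in tdTomato (adjusted p = 0.0237 and 0.0437). *Asns* lost its call without tdTomato 4a (adjusted p = 0.0627), iCreb5 3a (0.0602), iCreb5 3b (0.0534) or iCreb5 3c (0.0594). *Nupr1* kept its call without tdTomato 3a, iCreb5 4a, iCreb5 5 or iCreb5 6 and lost it without any of the other 8 libraries (adjusted p up to 0.0994) and with edgeR (0.052). The list had a median log2 change of -0.25, camera adjusted p = 0.00518, and adjusted p = 0.55 with an estimated correlation. Its call was lost without litter 3 (adjusted p = 0.106) and in litters 4 to 6 (0.101). Of 14 measured glycolysis and hypoxia genes the carbonic anhydrase gene *Car9* was lower, 2.25-fold higher in tdTomato (2 lower when adjusted over the list alone). Camera adjusted p was 0.00518 for that list, with adjusted p = 0.342 with an estimated correlation, and its call was lost without litter 3 (0.351), in litters 4 to 6 (0.438), with litter 3 averaged (0.0746) and with quantile normalisation (0.0595). Of 14 p53 response genes the kinase gene *Plk2* was higher, 1.97-fold (adjusted p = 5.83e-05), and it alone passed when adjusted over the list alone (camera adjusted p = 0.741). Of 14 interferon response genes *Ifit1* was higher, 7.37-fold (adjusted p = 0.0274), alone also when adjusted over the list alone (camera adjusted p = 0.128, but 0.0405 without iCreb5 3c, 0.0209 without litter 3 and 0.0328 in litters 4 to 6). *Ifit1* lost its call without tdTomato 3a (adjusted p = 0.0512), tdTomato 3c (0.0505), iCreb5 3b (0.0547) or iCreb5 6 (0.0661), and was 4.56-fold higher without tdTomato 5b. Of 4 measured sex-linked genes none passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.516, but 0.0317 in litters 4 to 6), and their levels put 2 of 6 iCreb5 and 3 of 6 tdTomato libraries as female.

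Markers of other cell types moved apart from each other. All 12 markers of macrophages and other leukocytes were higher in iCreb5, also when adjusted over the list alone, with a median log2 change of 2.75. The macrophage growth factor receptor gene *Csf1r* (chromosome 18, 61100598 to 61132149) rose 8.09-fold, from 98.4 ± 43.8 to 828 ± 417 (n = 6, adjusted p = 6.04e-05). The pan-leukocyte gene *Ptprc* was 22.5-fold higher, the mannose receptor gene *Mrc1* 8.36-fold and the complement gene *C1qa* 7.73-fold. Camera gave an adjusted p of 6.14e-21, adjusted p = 0.0262 with an estimated correlation, and all 12 were higher without tdTomato 3a and 5b or without iCreb5 5 and 6. The median was 2.44 within litter 3 and 2.99 within litters 4 to 6. Of 12 endothelial genes 5 were higher and 0 lower (10 and 1 when adjusted over the list alone), with a median log2 change of 0.99. The median was 1.46 within litter 3 (5 higher) and 0.72 within litters 4 to 6 (1 higher and 1 lower), and 0 genes passed without litter 3. In litter 5 the mean log2 level of the list was 7.05 in iCreb5 and 7.25 in tdTomato. The adhesion gene *Pecam1* was 3.46-fold higher (adjusted p = 0.00154) and the receptor gene *Tek* 1.93-fold (adjusted p = 0.0124). The calls for *Tie1* (3.40-fold, adjusted p = 0.0359), *Cdh5* (3.09-fold, adjusted p = 0.0444) and *Kdr* (2.28-fold, adjusted p = 0.0298) were lost when 1 of 10, 10 and 7 of the 12 libraries was left out (adjusted p up to 0.0886, 0.114 and 0.0726). *Tie1* held without tdTomato 4a or iCreb5 5, *Cdh5* without tdTomato 5b or iCreb5 5, and *Kdr* without tdTomato 3c, 5b or 6d or iCreb5 4a or 5. Camera gave the endothelial list an adjusted p of 2.3e-05, and adjusted p = 0.186 with an estimated correlation. Without tdTomato 3a and 5b, 3 endothelial genes were higher, and without iCreb5 5 and 6 it was 6.

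Of 10 measured neuronal genes 3 were higher and 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.00237, adjusted p = 0.101 with an estimated correlation). The LIM homeobox gene *Isl1*, which hindlimb mesenchyme also expresses early, was 6.46-fold higher, and the neurofilament genes *Nefl* and *Nefm* were each 6.27-fold higher (adjusted p from 3.52e-08 to 3.44e-07). The growth-cone gene *Stmn2* was 3.14-fold higher in tdTomato (adjusted p = 0.000283). Of 11 measured genes of Schwann cells and melanoblasts 2 were lower and 0 higher (5 lower when adjusted over the list alone). The neural crest regulator *Sox10* was 3.57-fold and *S100b* 2.53-fold higher in tdTomato. Camera gave an adjusted p of 0.00112 for that list, and adjusted p = 0.0291 with an estimated correlation, but 0.0734 in litter 3 alone. Of 11 measured epidermal genes the signal gene *Fgf8* (3.21-fold) and the keratin gene *Krt8* (2.92-fold) were higher in tdTomato, the same 2 when adjusted over the list alone (camera adjusted p = 0.239). *Krt8* lost its call without tdTomato 3b (adjusted p = 0.0503), tdTomato 3c (0.059), tdTomato 4a (0.0563), iCreb5 3a (0.0588) or iCreb5 3c (0.0516). None of 14 measured skeletal muscle genes and none of 7 measured red cell genes passed, over all genes or when adjusted over the list alone. Camera gave adjusted p of 0.239 and 0.706, and muscle passed without iCreb5 3c (0.0318), without litter 3 (0.0153), in litters 4 to 6 (0.00461) and with litter 3 averaged (0.0102). Red cells passed in litter 3 alone (0.0445).

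Whether the effect of iCreb5 differed between litter 3 and litters 4 to 6 was tested as an interaction. As examples chosen after their values were seen, log2 changes in litter 3 and in litters 4 to 6 were 4.54 and 5.57 for *Tbx22*, 2.79 and 2.49 for *Wnt16*, -2.24 and -1.82 for *Matn1*, and 3.12 and 2.92 for *Csf1r*. For *Nkx3-2*, not called, they were 0.68 and -0.36. No gene passed in limma with Benjamini-Hochberg adjustment (0 of 16733), and 1500 genes had an unadjusted p under 0.05. That is more than the share of 0.05 that chance gives. Genes vary together over the same libraries, so the excess does not count real differences, and its cause was not tested. In simulated data, with the same spread between libraries for every gene, that term recovered 14% of 2-fold and 84% of 4-fold differences. Smaller differences between litters would mostly be missed, and more so in genes with a wider spread.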

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

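The tests of the leukocyte markers against the other lists, by litter and by their joint variation, the first 2 tests of the cartilage genes and the test of distal Hox genes were chosen only after the result was seen. The sex covariate was also added after seeing the data.

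In 17 of 294 groups of 6 libraries examined, a library lay far from the other 5, where chance gives about 1 in 20 and so 15. Depth of iCreb5 3c was 49.21 M reads (M for 1000000), with the next at 30.88 M. The mitochondrial share of tdTomato 5b was 2.368%, with the next at 1.143%. On the log2(value + 1) scale, tdTomato 5b was also lowest for *C5ar1* (1.334, next 3.603), *Itgbl1* (7.043, next 7.425), *Mmp16* (10.51, next 11.16) and *Ifit1* (0, next 3.405), and highest for *H19* (16.25, next 15.04). Its littermate iCreb5 5 was lowest for *Prg4* (8.819, next 9.751), *Cdh5* (4.9, next 7.246) and *Tie1* (4.858, next 7.751), and highest for *Klk10* (5.721, next 4.438). Library tdTomato 3a was lowest for *Barx1* (7.792, next 8.386) and *Nkx3-2* (5.829, next 6.86), and tdTomato 3b for *Hoxd11* (7.226, next 7.85). Library iCreb5 4a was lowest for *Prrx1* (11.58, next 11.98) and *Sox10* (4.007, next 5.396), and iCreb5 3b for *Hist1h2br* (0, next 2.599).

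All 12 leukocyte markers were higher in iCreb5, although these cells were sorted for GFP. A smaller share of mesenchyme would raise every other cell type alike. It is argued against by a difference of 2.73 between the leukocyte median log2 change and that of 53 markers of 5 other cell types. The difference has a bootstrap SE of 0.222, which comes from resampling genes that vary together and does not measure the spread between libraries. Endothelium, left out of these 5, had a median of 0.99. In the mean log2 level of the leukocyte markers, iCreb5 lay above tdTomato in 4 of 4 litters (by 2.52, 2.25, 3.32 and 3.72). The groups did not overlap in it (lowest iCreb5 7.197, highest tdTomato 5.975), so that count was fixed and decides nothing about batch. Leukocytes among the sorted iCreb5 cells, more in some libraries than in others, remain a candidate explanation. Within iCreb5 the markers had a mean pairwise correlation of 0.806, above all 10000 random lists matched on expression (95th percentile 0.121). Joint variation also occurred without a rise. The correlation estimated by camera was 0.813 for red cells and 0.478 for skeletal muscle, neither with a called gene, and 0.572 for leukocytes. For the remaining lists of other cells it ran from 0.0164 to 0.318. The joint variation therefore does not tell what raised the leukocyte markers. Normalised counts of the abundant *Csf1r* (828 in iCreb5) and *C1qa* (326) lay below those of mesenchymal genes such as *Prrx1* (4158). Counts of different genes are not scaled to each other or to cells, so they do not give the share of leukocytes. Recruitment of leukocytes by the transgene, or a difference in how the GFP and tdTomato gates let such cells through, stays open and untested.

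Cartilage genes were lower in iCreb5, 21 of 24 of them. A fall of all these genes by a common factor, which fewer of the same chondrocytes would give, is argued against by the standard deviation of their log2 changes (0.583, where the highest over all splits of the deviations within groups was 0.391). Their mean log2 level fell in 4 of 4 litters (-1.50, -1.49, -1.09 and -1.24). The groups did not overlap in it (highest iCreb5 11.061, lowest tdTomato 12.054), so that count was fixed and decides nothing about batch. A difference in sex is argued against by 21 of 21 genes staying lower with sex as a covariate. A smaller share of chondrocytes stays open where other sorted cells also express some of these genes, which would make the falls unequal. So does lower expression in the same cells, and no value measured here separates the 2.

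Hox genes of paralogue groups 10 to 13 rose (6 of 9) while those of groups 1 to 9 had a median log2 change of -0.50 (4 of 23 lower, or 2 to 5 under other scalings, with no change of sign). For more distal tissue in the iCreb5 sorts, the mean log2 change of *Hoxa13* and *Hoxd13* minus that of *Hoxd10*, *Hoxd11* and *Hoxd12* was -0.796 (SE 0.0533, exact permutation p = 0.00217). It subtracts the 3 Hox genes with the largest rises, chosen after these were seen, so it decides nothing and more distal tissue stays open. A lower share of proximal tissue in the iCreb5 sorts may contribute, since the proximal genes *Meis1* and *Meis2* had a mean log2 change of -0.271 (SE 0.110, exact permutation p = 0.0346), though neither passed alone (adjusted p = 0.277 and 0.305). Whether Creb5 acts on the Hox clusters was not tested, nor was a difference between the sorts in the shares of forelimb and hindlimb tissue.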

How the results depend on the processing

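The sex and leukocyte covariates and the omission of tdTomato 3a and 5b or of iCreb5 5 and 6 were chosen only after the result was seen. Lower genes numbered 728 with litter as the replicate block, 775 with the title number as the replicate block and 732 with DESeq2, against 477. For these 3 the cause was not tested. The litter block changed no gene list's call, and of 102 called genes named in the text it lost 1, *Plagl1* (adjusted p = 0.0514). With litter 3 averaged to 1 value per group as well, 494 were higher and 388 lower, and 18 of the 102 were lost: *Gdf6* (0.0524), *Grem1* (0.0688), *Maf* (0.102), *Car9* (0.119), *Dlx6* (0.145), *Fgf8* (0.0793), *Mfap5*, *Aurkb*, *Asns*, *Tie1*, *Cdh5*, *Kdr*, *Krt8*, *Hoxa11*, *Hoxc4*, *Hoxc5*, *Hoxd1* and *Mest*. Without litter 3, 85 were higher and 57 lower, while the same 6 libraries with litter as the replicate block gave 330 higher and 380 lower. The cause was not tested. Without litter 4, 296 were lower, and in litter 3 alone 397 were higher and 296 lower. For these sets the filter was applied anew to the libraries kept, unlike the 395, 292 and 320 of the report, which used the 16733 genes. Leaving out single libraries gave 487 to 708 higher and 370 to 517 lower genes. The leukocyte score separates the groups nearly completely (r with group 0.927), so as a covariate it takes up most of the contrast: 14 genes were higher and 5 lower, the leukocyte list had an adjusted p of 0.944, and *Ccl4* (-0.34), *Ptprc* (-1.72) and *C1qa* (-0.32) turned to falls with adjusted p of 0.98, 0.923 and 0.961. The interzone list passed with quantile normalisation (0.0446), without litter 5 (0.0343) and in litter 3 alone (0.0239), and ran from 0.0372 to 0.237 without single libraries. The articular list passed with no filter (0.0417), without litter 3 (0.024) and in litters 4 to 6 (0.0266), and ran from 0.0352 to 0.219. For both lists the cause was not tested. The list of cAMP and immediate early genes passed as higher without litter 3 (0.0201) and in litters 4 to 6 (0.00986), and turned to lower with the leukocyte covariate (6.77e-05) and without iCreb5 5 and 6 (0.0139). With the leukocyte covariate the limb position (0.292), stress response (0.38), glycolysis (0.104), and Schwann cell and melanoblast (0.188) lists lost their calls. The chondrocyte, hypertrophic and osteoblast lists kept their direction and call in all settings run, and without single libraries ran from 9.42e-40 to 3.5e-34, 2.26e-08 to 1.85e-06 and 1.33e-15 to 3.01e-12. The leukocyte list ran from 1.67e-25 to 1.95e-17. No called gene changed sign in any setting except the leukocyte covariate (63 of 1125). Of the 102 called genes named, 31 passed without litter 3 and 8 with the leukocyte covariate, and 61 passed in every other setting. The interaction stayed at 0 genes with the other pseudocounts and with no filter. Depth limits weak genes: the 3-read level of tdTomato 3a was 8.38 deposited units.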

Other observations

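The imprinted genes were listed and their tests were chosen only after the result was seen. The tests on risers and the leukocyte score, *Prg4*, neighbouring genes, the Rosa26 region and other splits of the libraries were set before their results were seen.

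Imprinted genes, which are expressed from only the mother's or only the father's copy, were lower as a group in iCreb5. Of the 7 that drew attention to them, 6 were lower and 1 was higher. Of 46 other measured imprinted genes, 8 were lower, 0 were higher and 38 did not pass. Among these, chosen after their values were seen, the noncoding *H19* was 1.99-fold higher in tdTomato (adjusted p = 0.00837) and *Mest* 1.43-fold (adjusted p = 0.0058). The growth factor gene *Igf2* was 1.43-fold higher in tdTomato (adjusted p = 0.0203), with its call lost without iCreb5 3a (0.0517) or iCreb5 4a (0.0527). *Dlk1* (1.43-fold) lost its call without any library but tdTomato 3a, iCreb5 5 or iCreb5 6 (adjusted p up to 0.0843), and *Plagl1* (1.84-fold) without any but tdTomato 3b, iCreb5 3a or iCreb5 3c (adjusted p up to 0.114). The hypothesis that imprinted genes fall as a set gave a median log2 change of -0.257 over the 46 genes, below all 10000 random lists matched on expression (lowest -0.193). With an estimated correlation between genes (0.0239) camera gave p = 0.00532 for these 46. The median was -0.22 in litter 3 and -0.27 in litters 4 to 6. Cell types shifted in the same libraries, with median log2 changes of 2.75 for leukocyte and -1.41 for cartilage genes. Within groups the mean level of the 46 genes had r = 0.565 with the leukocyte score and -0.176 with the cartilage score over 12 libraries. A fall through more leukocytes or fewer chondrocytes would give the opposite signs. No interval was computed for either r, and the cartilage score varied little within iCreb5 (10.779 to 11.061, lowest tdTomato 12.054). These correlations therefore cannot decide whether such shifts lower the set. Shifts of other cell types were not tested.

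The Hox genes outside the limb position list that passed, chosen after their values were seen, were *Hoxc4* (2.12-fold higher in tdTomato, adjusted p = 0.00516), *Hoxc5* (1.82-fold, adjusted p = 0.0141), *Hoxc6* (1.81-fold, adjusted p = 0.0366) and *Hoxd1* (2.05-fold, adjusted p = 0.0408). *Hoxc6* lost its call without tdTomato 3a, 3b, 5b or 6d or iCreb5 4a, 5 or 6 (adjusted p up to 0.0871), and *Hoxd1* without any library but tdTomato 3c, tdTomato 6d or iCreb5 3a (adjusted p up to 0.0965).

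Leukocyte transcripts may make up part of the rises: of 636 risers outside the leukocyte list, 37 (5.82%) followed the leukocyte score within groups with r above 0.7, against 74 of 15608 genes not past the threshold (0.474%, Fisher's exact p = 7.85e-25). That test counts genes as independent, though they vary together over the same 12 libraries, so its p does not measure the spread between libraries. For *Prg4* the values gave no sign of a rise through leukocyte transcripts, with r = -0.164 within groups over 12 libraries (permutation p = 0.641). No interval was computed for this r, so such a rise is not excluded. Library iCreb5 5, lowest of its group for *Prg4* (8.819, next 9.751), had a leukocyte score of 8.699. The value of r without that library was not computed. Spearman's rho was -0.0909 (permutation p = 0.790), and r was -0.178 without the 2 libraries farthest out in the leukocyte score. With the score as covariate its log2 change was 3.79 ± 0.71 (SE), but its call was lost (adjusted p = 0.0626). That score follows the groups closely (r = 0.927), so the covariate fit separates little.

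Neighbouring genes changed together more often than reassigned calls. Of 14316 protein-coding genes in chromosome order, 95 adjacent pairs were called in the same direction, against a median of 41 and a highest value of 68 in 10000 reassignments. The runs included *Hoxd13* to *Hoxd10*, the Ms4a and C1q genes, and *Dmp1*, *Ibsp* and *Spp1*, so shared cell types or shared regulation could each contribute. Strain variants linked to the Rosa26 alleles were tested within 20 Mb of Rosa26 on chromosome 6. There 7.98% of genes were called (19 of 238), against 6.70% elsewhere (Fisher's exact p = 0.432). A window of 238 genes could not hold most of the calls whatever the cause. No interval was computed for the difference in shares, so an excess of calls through linked variants is not excluded.

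Among 100 of 462 splits of the 12 libraries into 6 and 6, 1 gave as many called genes as the real 1125, the real split itself. The highest other gave 56. A share of 1 in 100 is the smallest these splits allow, so chance is unlikely at that level but not excluded. They also treat the 12 libraries as exchangeable, although litter 3 gave 3 of each group. Among the 80 splits that part each litter equally, with litter as the replicate block, 1 gave as many as the real 1587, and the highest other gave 12. Litter 3 alone has 10 splits (real 687, highest other 1) and litters 4 to 6 have 4 (real 688, highest other 0), too few for a share under 0.05. For the interaction all 100 of 200 divisions drawn gave at least the real 0 genes, as any split must, so this decides nothing. Over the other divisions the median was 0 and the highest 266, and what gave the 266 was not tested.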
